A study of Homo sapiens with 9 samples.

How the data were processed

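RNA was sequenced from 9 libraries of MV4-11 cells, grouped as the labels give them. There were 3 libraries each of cells kept for 18 h in DMSO, in JB170 at 100 nM and in alisertib at 1000 nM. RNA was purified with miRNeasy columns and a DNase step, and directional libraries were made after poly(A) selection with NEBNext kits, per the labels' protocols. FastQC, TopHat2 2.1.1, Bowtie2 2.3.2 and the genome build hg19 are named per the submitters' processing notes. The counting of reads, the normalization, the test, its filter and the adjustment are not given in the sources used here.

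The values used were those of the authors' table of comparisons, which gives per gene a log2 fold change, a p-value and an adjusted p-value of DMSO against each treatment, per the file headers. It also holds 1 column of mean log2 CPM deposited by the authors, whose libraries the header does not name; its values run from -0.72 to 12.61 with a median of 4.75. Each log2 value is thus the authors' own, apart from the change of sign given below. Each p-value against DMSO is the authors' deposited one. The table has 13410 genes, after 80 entries with 5 repeated identifiers were reduced to 1 each. The adjusted p-values have the ratios to the p-values that the Benjamini-Hochberg method gives over 16812 tests, so 3402 further tests of the authors are not analysed here. From those ratios at least 5 genes with JB170 and 852 with alisertib passed among all tests of the authors, of which 4 and 794 were analysed here. CDKN1A and the mitochondrially encoded genes are not analysed here. Values per library were not used here, so the depth is unknown, no interval for counting error was computed, and no library was compared with another.

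The table holds 4 comparisons. The column headed A1000 was read as alisertib because of its dose of 1000 nM, and the column headed JB170 as JB170. The columns headed A100 and MK have no group in the labels and were left out of the comparisons of the report. The headers name DMSO before the treatment in each comparison, yet the JB170 column correlated negatively with the others as deposited. Over all genes Pearson's r was -0.49 with the column A1000, -0.53 with A100 and -0.45 with MK, while the other pairs gave 0.53, 0.51 and 0.49. Simulated comparisons with the same DMSO libraries gave 0.51 when coded alike. The direction of each column was worked out from the size of the implied standard error, which is larger for genes with fewer reads in the treated group. Genes with an absolute log2 fold change of at least 1 and a mean log2 CPM between 0 and 4 were used. The log2 standard error of positive minus negative genes was 0.39 in the column A1000, 0.31 in A100 and 0.30 in MK (permutation p = 1e-04 each, the smallest that 10000 permutations can give), against 0.85 in simulated data coded as DMSO minus treated and -0.85 in the opposite coding. In the JB170 column it was 0.01 (permutation p = 0.106), which leaves that column's direction to the correlations. All columns but JB170 were therefore multiplied by -1, so that each value is treated minus DMSO. This direction is inferred, and no header states it. It also rests on a setting of the simulation, where the mean log2 CPM was taken over the DMSO and JB170 libraries. The libraries behind the deposited mean are not named, and another choice could change or turn the simulated values.

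No test against DMSO was computed here. Had the values been counts or normalized values per library, a count model or limma-trend would have been fitted; for a table of comparisons alone, the authors' adjusted p-value was taken as it is, with a gene called at an adjusted p under 0.05. The tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined, and so was this choice for a table of comparisons. The test of alisertib minus JB170 and its alternatives were chosen after the values were seen. In it, the difference of the log2 fold changes was divided by a standard error implied by the authors' log2 fold changes and p-values. A gene's own implied error was used where its absolute z was at least 1, and otherwise the running median over 60 bins of mean log2 CPM. The DMSO libraries that both comparisons share were not taken off, which makes the error too large, and a second version took them off. P-values were two-sided from the normal distribution and adjusted by the Benjamini-Hochberg method over the 13410 genes. In simulated data for this comparison, over 13410 genes, the first version called 19.1% of genes changed by a log2 fold of 0.5, 78.8% at 1 and 89.4% at 1.5, and 0 of 13210 unchanged genes. The SD of its statistic was 0.660 over unchanged genes, where 1 would be exact. The second version called 61.8%, 92.4% and 97.0% and 10 unchanged genes, with an SD of 0.933.

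Named genes were, per comparison, the 8 with the largest increase and the 8 with the largest decrease among those called with a mean log2 CPM of at least 3, leaving out sex-linked genes and symbols that start with LOC, LINC, MIR, SNORD, SNORA, RNU or the prefix of a clone. RN7SK has none of these prefixes and was kept. To these were added the 3 members with the smallest p of each list past the threshold, and 12 genes always given. The part of the rule that asks for libraries without overlap could not be applied. ANKRD30BL lies on chromosome 2 (132147591 to 132257969, GRCh38). Gene positions are from GENCODE 29, on GRCh38, whereas hg19 is the build named per the submitters' processing notes; 13181 identifiers matched it.

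Of 26 gene lists written beforehand, 24 had at least 5 measured members. They were tested with cameraPR of limma 3.58.1, with a preset correlation between genes of 0.01. The statistic was a signed z worked out from the authors' p-value and the inferred direction of the log2 fold change. In alisertib minus JB170 it was the z of the approximate test. Adjustment was over 72 tests, 24 lists in 3 comparisons. A correlation estimated per list needs values per library and was not run, so the preset value of 0.05 was the only check of this kind: 5 of the 9 lists past the threshold with alisertib held with it. Members were counted over all genes and adjusted over the list alone. On simulated unchanged data 2.35% of lists had a p under 0.05 over 200 draws of 24 lists. The genes in these draws were independent, so the draws could not show what a correlation between members does. Ribosomal protein and histone genes have near-identical copies, so reads may be shared between them and their values are uncertain.

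The overlap between compounds was set against 100 simulated pairs of unchanged groups with the same DMSO libraries, over 9321 genes with a mean log2 CPM of at least 3. Alternatives were other thresholds, adjustment over the genes of the table, a minimum mean log2 CPM of 3, a fold of 1.5 in addition, the JB170 column read in the direction of the others, the shared DMSO libraries taken off, and for lists another preset correlation, ranks, and the log2 fold change as the statistic together with the minimum mean log2 CPM of 3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.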

Results

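Gene expression was measured by RNA sequencing in MV4-11 cells, a human acute monocytic leukaemia line. The cells were treated for 18 h with the vehicle DMSO, with 100 nM JB170 or with 1000 nM alisertib. JB170 is the degrader of Aurora A that the title of the series refers to, and alisertib is an inhibitor of the kinase activity of Aurora A. Each of the 3 groups had 3 libraries, 9 in all. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The values analysed were those of the authors' deposited table, which gives a log2 fold change, a p-value and an adjusted p-value against DMSO for 13410 genes. Values per library were not analysed here, so the depth is unknown and no error per group can be given. All changes are written as treated minus DMSO, a direction that was worked out from the values themselves, because the JB170 column runs opposite to the alisertib column as deposited. Were the JB170 column read the other way, every direction given for JB170 would turn and every difference between the compounds would change. The direction of the alisertib column was inferred as well, with a simulation whose setting could change or turn it. Were all columns to turn together, every direction given here would turn.

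The first question was what happened to the transcript of the target. AURKA, which encodes Aurora A (ENSG00000087586, on chromosome 20 from 56369389 to 56392337 on the minus strand in the GRCh38 annotation), changed by 0.04 on the log2 scale with JB170 in the authors' deposited table (p = 0.650, adjusted p = 1). With alisertib, AURKA was higher by 0.49 in the authors' deposited table (adjusted p = 1.59e-06). The difference between the compounds was 0.45 (95% interval 0.21 to 0.69), which missed the threshold in the approximate test (adjusted p = 0.0731) and passed it when the shared DMSO libraries were taken off the error (adjusted p = 7.54e-05). The authors' deposited table gave AURKB, the kinase of the chromosomal passenger complex, at -0.01 with JB170 and -0.10 with alisertib, neither past the threshold. CRBN, which encodes cereblon, the substrate receptor of a ubiquitin ligase, stood at -0.07 with JB170 and -0.09 with alisertib in the authors' deposited table, and neither passed.

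The second comparison asked which transcripts differed after 100 nM JB170. Few were called: 4 genes had an adjusted p under 0.05 in the authors' deposited table, 3 higher and 1 lower. An unadjusted p under 0.05 was found for 405 of 13410 genes (3.02%). The signed z of JB170 had an SD of 0.872 over genes with a mean log2 CPM of 3 or more. Unchanged genes would give 1 if the p-values were exact, so these may be conservative. A simulated exact test of alisertib against DMSO, with 200 changed genes, called 57.4% of genes changed by a log2 fold of 0.5. The adjusted threshold is stricter where few genes pass, so this share may be too high for JB170. Smaller changes and some larger ones may thus have been missed. For example, CHAC1 stood at -0.70 with JB170 in the authors' deposited table with an adjusted p of 0.130. ANKRD30BL was higher by 2.17 on the log2 scale (adjusted p = 6.78e-16 in the authors' deposited table). HFM1, a DNA helicase gene of meiotic recombination, was higher by 0.75 (adjusted p = 1.66e-13, authors' deposited table). SLCO5A1, a member of the organic anion transporter family, was higher by 0.51 (adjusted p = 0.00213, authors' deposited table). SPTLC3, a subunit of serine palmitoyltransferase, was lower by 3.16 (log2 fold change -3.16, adjusted p = 0.00582, authors' deposited table) at a low mean of 1.07 log2 CPM, and was chosen after its values were seen. In the authors' deposited table RN7SK (0.63, p = 0.00135, adjusted p = 0.873), RMRP (0.71, p = 0.00485, adjusted p = 1) and the ribosomal RNA RN28S1 (0.66, p = 0.0116, adjusted p = 1), which lack a poly(A) tail, were not past the threshold with JB170. RMRP and RN28S1 were chosen after their values were seen.

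Among the gene lists, that of ATF4 targets and the unfolded protein response was lower with JB170 as a group. Its median over 46 measured members was -0.08 on the log2 scale (limma's cameraPR, adjusted p = 2.03e-06), with 34 members below 0 and 12 above. None of the 46 members was called on its own over all genes by the authors' test, 8 had an unadjusted p under 0.05, all of them lower, and 3 passed when adjusted over the list alone. CHAC1, a glutathione-degrading enzyme induced by ATF4, stood at -0.70 in the authors' deposited table (p = 5.43e-05, adjusted p = 0.130). ASNS, which makes asparagine, stood at -0.33 (p = 0.000353) and DDIT4, an inhibitor of mTORC1 signalling, at -0.39 (p = 0.000439) in the authors' deposited table, neither past the adjusted threshold.

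Cytosolic ribosomal protein genes were also lower as a group with JB170, by a small amount: the median over 67 members was -0.05, 60 members lay below 0 (adjusted p = 8.16e-05), and no member was called or had an unadjusted p under 0.05. RPL41 (-0.13), RPS18 (-0.14) and RPS29 (-0.14) had the smallest p-values of the list in the authors' deposited table. The cameraPR adjusted p was 0.0394 with a preset correlation of 0.05. If the members move together between libraries by more than the preset value, these p-values are too small. The list lost its call with the log2 fold change as the statistic over genes with a mean log2 CPM of 3 or more (adjusted p = 0.0636). The heat shock list passed narrowly (median -0.02 over 19 members, adjusted p = 0.0493) and was not past the threshold in 3 of the other settings, with adjusted p from 0.115 to 0.208. Its members with the smallest p-values were CHORDC1 (-0.22), HSPA1A (-0.19) and SERPINH1 (-0.22) in the authors' deposited table, none of them called.

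Cell cycle lists did not pass with JB170. The G2/M and mitosis list had a median of 0.04 over 73 members (adjusted p = 0.204), and the S phase and DNA replication list a median of -0.01 over 70 members (adjusted p = 0.644). No member of either list was called in the authors' deposited table, over all genes or over the list alone, and 1 had an unadjusted p under 0.05: PLK1, the mitotic kinase activated by Aurora A, at 0.20 (p = 0.0157). CCNB1 stood at 0.06, CCNE1 at 0.00, CCNE2 at -0.02, MKI67 at 0.06, TPX2 at 0.04, MYC at -0.03 and MDM2 at 0.06 in the authors' deposited table. CDKN1A is not analysed here. The p53 target list had a median of -0.02 (adjusted p = 0.767), and the list of the cereblon ligase and its known substrates a median of 0.02 (adjusted p = 1.00). The remaining lists had adjusted p-values from 0.0735, for myeloid maturation and for the BCL2 family, to 0.948, for the leukaemic HOXA and MEIS1 programme.

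The third comparison asked the same of 1000 nM alisertib, and here many transcripts differed. The authors' deposited table held 794 called genes, 415 higher and 379 lower, with a median size of 0.43 on the log2 scale, a 1.35-fold change. In the list of G2/M and mitosis more genes rose than fell, and in that of ATF4 targets and the unfolded protein response more fell than rose. Of the genes with a mean of at least 3 log2 CPM, ANKRD30BL (1.46), UNC5B, a netrin receptor (1.35), HFM1 (1.27), CCNA1, the cyclin of germ cells and leukaemic myeloid cells (1.25), and RN7SK, the RNA that holds P-TEFb inactive (1.20), rose most in the authors' deposited table. MVP, the major vault protein (1.04), ANPEP, the myeloid surface peptidase CD13 (1.02), and DNAJB2 (1.01) followed in the authors' deposited table. RN28S1 (1.44, adjusted p = 9.66e-08) and RMRP (0.97, adjusted p = 0.00298), which like RN7SK lack a poly(A) tail and were chosen after their values were seen, also rose with alisertib in the authors' deposited table. FGR, a myeloid SRC family kinase, fell by 2.41 and was the gene with the largest decrease under this rule in the authors' deposited table (adjusted p = 2.22e-10). MYBPH (-1.25), CHAC1 (-1.23), KAZALD1 (-1.21), CITED4 (-1.10), APBB1 (-1.07), MYO7A (-1.07) and the fructose transporter SLC2A5 (-1.06) completed the 8 largest decreases in the authors' deposited table. Across these 16 genes the largest adjusted p, that of MYO7A, was 0.00376.

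**Figure D1:**
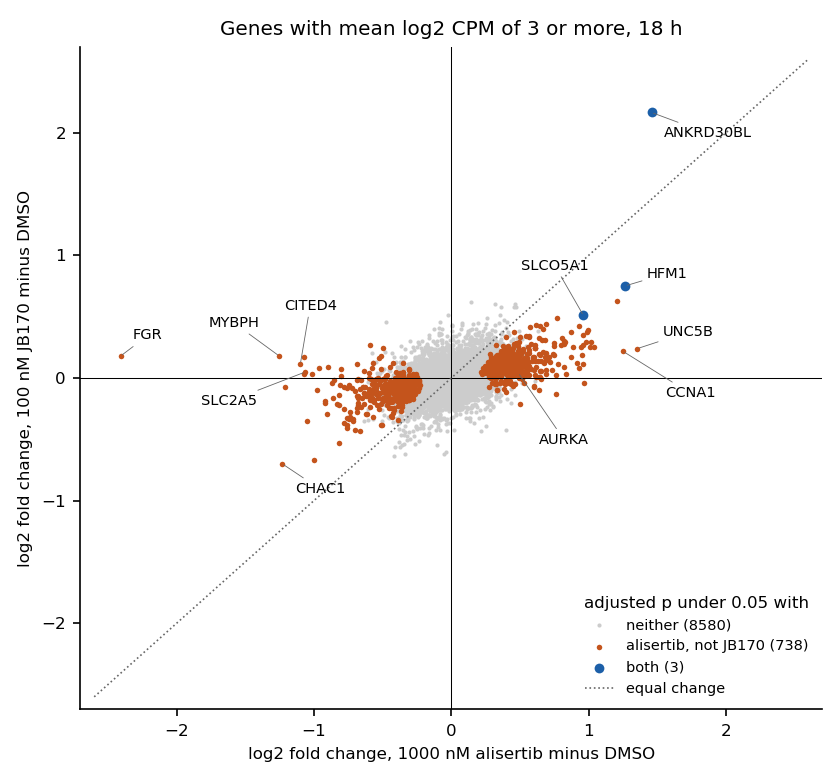
Log2 fold changes of the authors' deposited table for 9321 genes with a mean log2 CPM of 3 or more, 1000 nM alisertib against DMSO on the horizontal axis and 100 nM JB170 against DMSO on the vertical axis. Orange points are the 738 genes called with alisertib and not with JB170, blue points the 3 called with both, grey points the 8580 called with neither, and the dotted line marks equal change. The orange points spread more along the horizontal axis than along the vertical one, and most have the same sign on both. The shared DMSO libraries by themselves favour the same sign.

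The G2/M and mitosis list moved up with alisertib. Of 73 measured members 25 rose, 1 fell and 47 were not past the threshold; adjusted over the list alone, 28 rose and 3 fell. The median was 0.17 (adjusted p = 2.67e-12). HMMR, a spindle assembly factor, rose by 0.66 in the authors' deposited table (adjusted p = 2.14e-09). CDC20, the activator of the anaphase-promoting complex, rose by 0.51 (adjusted p = 1.34e-07) and PLK1 by 0.51 (adjusted p = 4.00e-08) in the authors' deposited table. CCNB1, which encodes cyclin B, rose by 0.41 in the authors' deposited table (adjusted p = 1.62e-05). TPX2, the spindle protein that activates Aurora A, stood at 0.19 and MKI67 at -0.12 in the authors' deposited table, neither past the threshold. The list of targets and partners, which also holds AURKB and CRBN, shares several of these genes. Of its 16 members 5 rose and 1 fell (7 and 3 adjusted over the list alone), with TACC3 at 0.29 in the authors' deposited table (adjusted p = 0.00999). The list's adjusted p of 0.0192 was lost in 3 of the other settings, at 0.0924 to 0.203.

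Genes of S phase and DNA replication moved the other way. Of 70 members 10 fell and 2 rose (16 and 3 adjusted over the list alone), and the median was -0.09 (adjusted p = 1.50e-05). RRM2, a subunit of ribonucleotide reductase, fell by 0.48, thymidylate synthase TYMS fell by 0.49 and the sliding clamp PCNA fell by 0.32 in the authors' deposited table, with adjusted p-values of 1.67e-07, 0.000688 and 0.00148. CCNE1 (-0.27) and CCNE2 (-0.32) were not past the threshold in the authors' deposited table. Replication-dependent histones had a median of 0.29 and did not pass as a list (adjusted p = 0.153); 4 of 48 members rose and 2 fell (6 and 2 adjusted over the list alone). Histone genes are near-identical copies and their transcripts mostly lack a poly(A) tail, so their values are uncertain.

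The list with the smallest p-value with alisertib was that of ATF4 and the unfolded protein response. Of 46 members 20 fell and 1 rose (25 and 2 adjusted over the list alone), with a median of -0.26 (adjusted p = 1.01e-16). In the authors' deposited table ASNS fell by 0.71 (adjusted p = 2.02e-11), DDIT4 fell by 0.76 (adjusted p = 8.49e-09) and SLC7A5, the large neutral amino acid transporter, fell by 0.49 (adjusted p = 6.67e-09). The ribosome biogenesis and MYC target list was lower by a median of 0.13 (median -0.13, adjusted p = 2.03e-06), with 49 of 56 members below 0, although only 3 members fell on their own over all genes and 4 adjusted over the list alone. The 3 genes that fell were UTP3 (-0.39), RRS1 (-0.33) and IMP4 (-0.30) in the authors' deposited table. MYC itself fell by 0.26 in the authors' deposited table (adjusted p = 0.0130).

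Interferon response genes were higher as a group with alisertib, with a median of 0.22 over 46 members (adjusted p = 0.000105), 6 members rising and none falling (7 and 1 adjusted over the list alone). SAMD9L rose by 0.96, IFI16, a DNA sensor, by 0.63 and SAMD9 by 0.56 in the authors' deposited table. Of 42 myeloid maturation genes 8 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.12, adjusted p = 0.00108). CSF1R, the receptor of macrophage colony-stimulating factor, rose by 0.69 and CD68, a lysosomal protein of macrophages, by 0.68, while FGR of the same list fell by 2.41, all in the authors' deposited table. The maturation list lost its call in 2 settings (adjusted p 0.0561 with a preset correlation of 0.05 and 0.110 with the log2 fold change as the statistic over genes with a mean log2 CPM of 3 or more). The heat shock list had a median of -0.12 (adjusted p = 0.00521; 0.0515 with the higher preset correlation), and 2 of 19 members fell, DNAJB1 (-0.29) and CHORDC1 (-0.38) in the authors' deposited table; the same 2 members fell adjusted over the list alone. HSP90AA1 of that list stood at -0.18 in the authors' deposited table, not past the threshold. The immediate early list had a median of -0.19 (adjusted p = 0.0489), a call lost in the other 4 settings (adjusted p 0.0785 to 0.262). Of its 31 members 5 fell and 1 rose (5 and 2 adjusted over the list alone). In it FOSL1 fell by 0.68 and JUND by 0.40, and DUSP6 rose by 0.33, in the authors' deposited table.

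Lists that did not pass with alisertib had these adjusted p-values: BCL2 family 0.0925, cytosolic ribosomal proteins 0.102, DNA damage checkpoint and repair 0.111, cyclins and their kinases and inhibitors 0.121, tetraploidy and YAP targets 0.318, and immature granule genes 0.409. Cholesterol synthesis was at 0.600, the leukaemic HOXA and MEIS1 programme at 0.677, the cereblon list at 0.680, NF-kB and inflammatory mediators at 0.688, glycolysis and hypoxia at 0.708 and p53 targets at 0.893. MDM2, a p53 target, stood at 0.06 in the authors' deposited table. Markers of other cell types gave 0.853 for the erythroid and megakaryocytic list and 1.00 for the lymphoid list, with 5 and 6 members measured. The epithelial, neuroblastoma or fibroblast list had 4 members measured and the mitochondrial list 0, and neither was tested. In 6 lists with JB170, 4 with alisertib and 6 in the difference between them, the median, the mean and the test did not all have the same sign, and none of these lists passed.

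**Figure D2:**
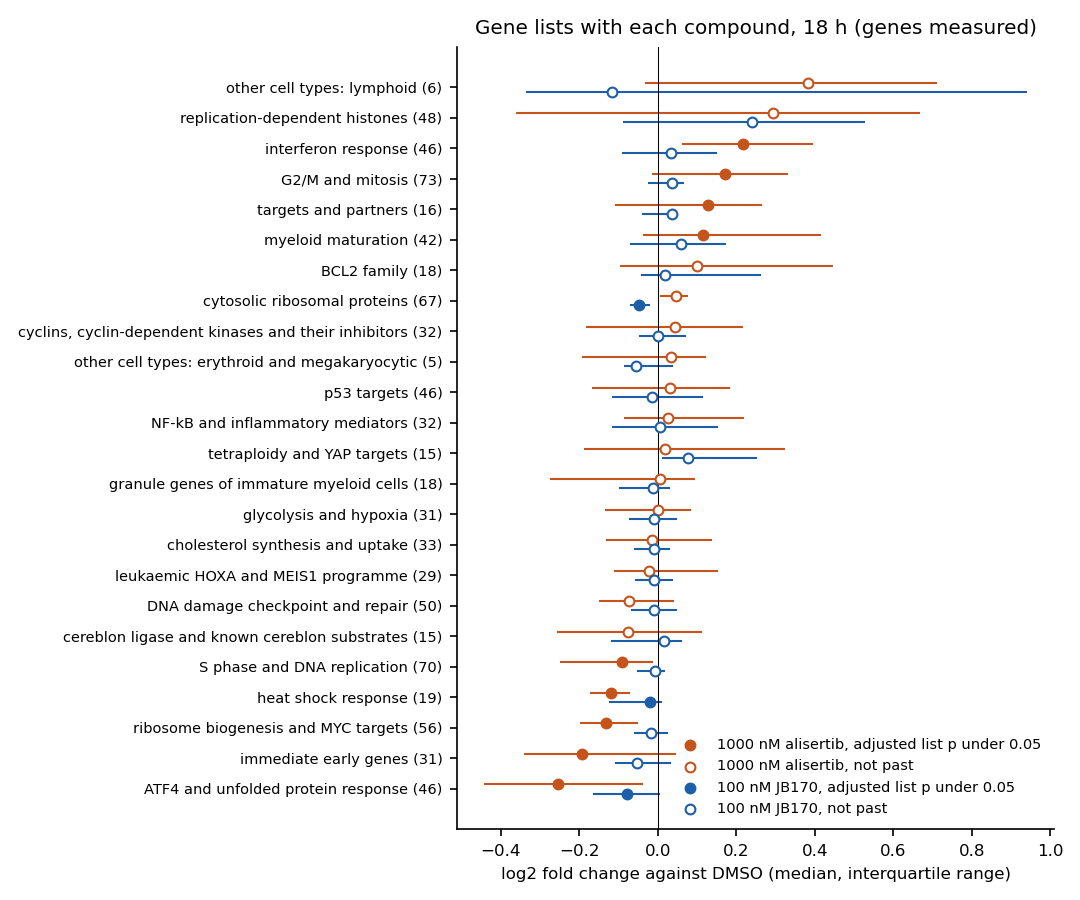
Median (point) and interquartile range (line) of the log2 fold change against DMSO over the members of each of 24 gene lists, for 1000 nM alisertib in orange and 100 nM JB170 in blue, from the authors' deposited table, with the number of genes measured in brackets. Filled points mark an adjusted p under 0.05. The median for ATF4 and the unfolded protein response is -0.26 with alisertib and -0.08 with JB170, and that for G2/M and mitosis is 0.17 and 0.04.

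The fourth comparison set the compounds against each other, at doses that differ (100 nM JB170 and 1000 nM alisertib), so it compares the compounds at those doses only. The approximate test called 38 genes, 17 higher and 21 lower with alisertib. All 38 were among the 794 genes called with alisertib against DMSO; the other 756 were not shown to differ in this test. The number rose to 367 (178 higher and 189 lower) when the shared DMSO libraries were taken off the error, and 295 of the 794 genes were then among them. It was 605 with the JB170 column read in the direction of the others. The difference for FGR was -2.59 (95% interval -3.38 to -1.80, adjusted p = 2.38e-07), that for MYBPH -1.43 (-1.72 to -1.14, adjusted p = 5.35e-18) and that for CHI3L1, a secreted glycoprotein of macrophages, -0.80 (-1.01 to -0.58, adjusted p = 1.39e-09). CITED4 (-1.21), APBB1 (-1.25), SLC2A5 (-1.11), HIVEP3 (-0.82) and ENDOD1 (-0.74) were the others named among those lower with alisertib, with adjusted p-values up to 0.0314. Higher with alisertib than with JB170 were CCNA1 (1.03, interval 0.75 to 1.32, adjusted p = 4.82e-09), BASP1 (0.85), the complement inhibitor CD59 (0.84), TXNIP, an inhibitor of thioredoxin (0.79), PHLDB1 (0.73), PLAC8 (0.67), the intermediate filament gene VIM (0.66) and the semaphorin receptor PLXND1 (0.62). With the JB170 column turned these values change and so would the choice of genes: FGR would stand at -2.23, ENDOD1 at -0.25, CCNA1 at 1.47 and HFM1, at 0.52 here, at 2.02.

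**Figure D3:**
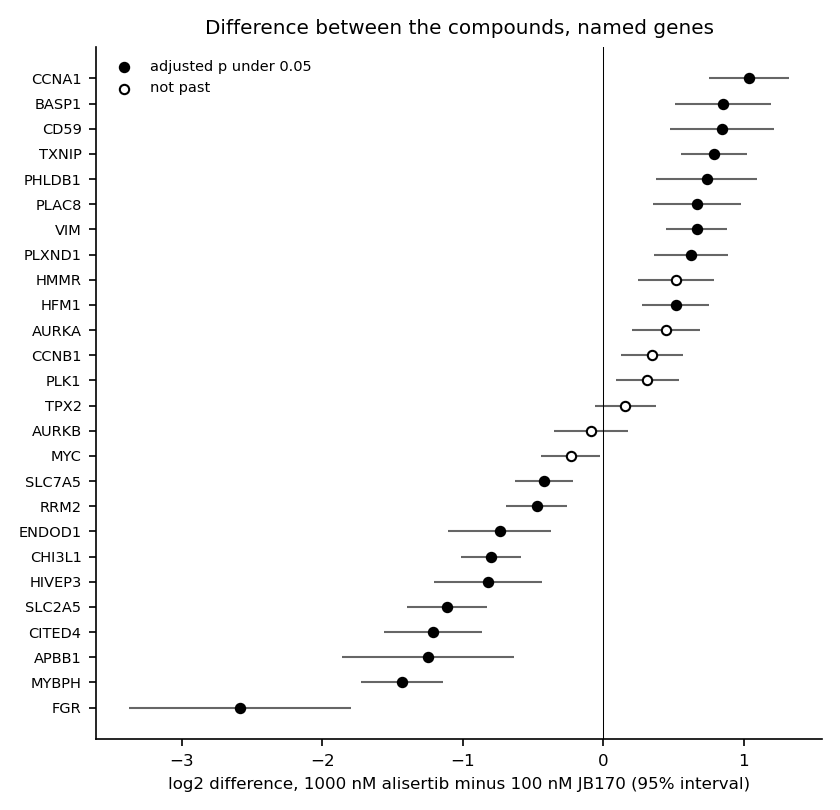
Difference of the log2 fold changes, 1000 nM alisertib minus 100 nM JB170, for 26 named genes, with its approximate 95% interval (line). Filled points passed an adjusted p under 0.05 and open points did not. FGR lies at -2.59 and CCNA1 at 1.03.

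By list, G2/M and mitosis genes were higher with alisertib than with JB170 by a median of 0.15 (adjusted p = 8.18e-12). No member passed over all genes in the approximate test, 20 were higher and 1 lower at an unadjusted p under 0.05, and 10 passed adjusted over the list alone. S phase genes were lower by a median of 0.10 (median -0.10, adjusted p = 1.25e-05), where RRM2 differed by -0.47 (adjusted p = 0.0132). ATF4 and unfolded protein response genes differed by a median of -0.14 (adjusted p = 3.74e-10), with SLC7A5 at -0.42 (adjusted p = 0.0260) past the threshold over all genes and 7 members past it adjusted over the list alone. As lists, ribosome biogenesis had a median difference of -0.11 (adjusted p = 2.62e-06), interferon response of 0.19 (adjusted p = 0.000495) and cytosolic ribosomal proteins of 0.09 (adjusted p = 1.70e-06). No member of these 3 lists was called over all genes in the approximate test, and 0, 1 and 0 passed adjusted over the list alone. At an unadjusted p under 0.05, 2 ribosome biogenesis genes were lower, 2 interferon response genes higher and 0 ribosomal protein genes either. The lists of targets and partners (median 0.12, adjusted p = 0.0320) and myeloid maturation (median 0.10, adjusted p = 0.0489) passed here but lost the call in 3 of the other settings each, with adjusted p from 0.128 to 0.162 and from 0.0813 to 0.610. The 1 member of the myeloid list called over all genes, FGR, was lower with alisertib, against the list's direction. Differences that missed the threshold leave a range open: the 95% interval was -0.06 to 0.37 for TPX2, -0.35 to 0.17 for AURKB, -0.44 to -0.02 for MYC, -0.40 to 0.40 for MDM2 and -0.37 to 0.32 for CRBN.

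The last comparison asked how far the responses overlapped. ANKRD30BL, HFM1 and SLCO5A1 were called with both compounds with the same sign, and 0 genes with opposite sign. Independent lists of these sizes would share 0.0928 genes among those higher and 0.0283 among those lower. All 3 genes were also higher in the columns headed A100 and MK. Whether reads of RNAs without a poly(A) tail were counted in HFM1, SLCO5A1 or ANKRD30BL stays open. For ANKRD30BL with JB170, the values argue only against RN28S1, RN7SK and RMRP as the sole source, and other such RNAs were not compared. Of the 794 genes called with alisertib, 709 (89.3%) had the same sign with JB170 (10.7% were the JB170 column read in the direction of the others). In 100 simulated unchanged pairs of groups the share was 87.5% to 92.9% among the 794 genes with the smallest p. Those genes were picked from noise alone, so this range cannot say what the shared libraries give for genes that alisertib changes. The genes higher with alisertib had a median of 0.44 with alisertib and 0.11 with JB170, and the lower genes -0.43 and -0.10. These genes were picked against the same DMSO libraries, which by itself moves their JB170 values to the same side. No simulated median was computed, so the JB170 medians cannot be read as the size of a response. Across 9321 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.473, against a mean of 0.502 in the simulations. The simulations hold no change with alisertib, and a change with alisertib alone lowers r, so these values of r cannot settle the overlap. The covariance of the log2 fold changes was 0.0129, against 0.00824 to 0.00977 in the simulations, so it lay above them by 0.00378 on average. The simulations gave every gene the median error of its expression level. Genes with a larger spread in the shared libraries would also raise the covariance, so this excess cannot settle the overlap either. The simulated values already hold the shared DMSO libraries, and those for independent lists do not. Since 3 DMSO libraries cannot be split into parts of at least 2, part of the excess of shared calls over independent lists may come from the shared controls.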

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

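Of the tests below, those on HFM1, SLCO5A1 and ANKRD30BL and those on the shared DMSO libraries were chosen only after the result was seen, and those on the expression level and the coding were written before.

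Signal was present in both columns of the authors' deposited table that have no group in the labels. In the column headed A100, 174 genes were called, 102 higher and 72 lower after the same change of sign, and 117 of them were called with alisertib with the same sign and 0 with the opposite one. Independent lists would share 3.16 higher and 2.04 lower genes. In the column headed MK of the authors' deposited table, 63 genes were called, 43 higher and 20 lower, and 46 were called with alisertib with the same sign and 0 with the opposite one, against 1.33 and 0.565 for independent lists. The comparisons appear to share DMSO libraries, which by itself raises such overlap, and what the columns stand for is not given in the labels, so no biological explanation was tested.

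ANKRD30BL, HFM1 and SLCO5A1 were higher in all 4 columns. Low values in the shared DMSO libraries alone would give each gene equal changes in the 4 columns, yet all 3 genes differed between columns by a heterogeneity test on the authors' log2 fold changes and the errors their p-values imply (p = 4.93e-27 for HFM1, 5.37e-16 for SLCO5A1 and 0.0141 for ANKRD30BL). Whether reads of RNAs without a poly(A) tail were counted in HFM1 and SLCO5A1 stays open. Among 13410 genes they ranked 2 and 6 by closeness of their 4 changes to the mean of RN28S1, RN7SK and RMRP, but this does not count for the explanation, since these RNAs were picked after their values were seen. For ANKRD30BL with JB170, reads of these 3 RNAs as the only source are argued against: its change exceeded theirs by 4.28, 5.01 and 4.22 standard errors (RN28S1, RN7SK and RMRP). In the other 3 columns this source stays open, as ANKRD30BL lay within 0.766 standard errors of the nearest of the 3 RNAs in each. The annotation places the ribosomal RNA pseudogene RNA5-8SP5 within ANKRD30BL, and its own RNA was not compared. A response of these transcripts to the compounds stays open and was not tested.

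The ATF4 and unfolded protein response list was lower with both compounds. High values in the shared DMSO libraries alone are argued against for alisertib, since the list was also lower in alisertib minus JB170 (adjusted p = 3.74e-10), which needs no DMSO library. For JB170 this explanation and a response cannot be told apart: the highest median in the other 3 columns was -0.11, against -0.08 with JB170, so no column is free of the decrease. A shift of genes of this expression level is argued against, since the list's median lay at percentile 0 of 10000 random lists matched on mean log2 CPM, whose lowest median was -0.05. A lower ATF4 programme after JB170 may be real, but rests on a comparison that the DMSO libraries could produce (-0.11 in the nearest other column).

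The JB170 column ran opposite to the others as deposited. Over 5308 genes with p above 0.2 in all 4 columns, where the shared DMSO libraries would give a positive correlation if the columns were coded alike, r with the column A1000 was -0.27, and that of A1000 with A100 was 0.25. An opposite response of the cells is thereby argued against, and the values are consistent with a column coded in the other direction (-0.27).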

How the results depend on the processing

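All alternatives reported here were chosen after seeing the data. Those planned before were not run because they need values per library: other normalizations (RLE or library size for TMM), low-count filters, DESeq2, the samples in the fit, the replicate block, glmTreat, leave-one-out, pseudocounts, fry and an estimated correlation. No paired analysis was possible because values per library were not used here, and other splits of the samples could not be tested either.

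Read in the same direction as the other columns, the JB170 column gave 1 higher gene in place of 3, 605 genes in the difference in place of 38, 0 shared genes in place of 3, a same-sign share of 10.7% in place of 89.3% among genes called with alisertib, and an r of -0.473 in place of 0.473, which follows from the change of sign. At an adjusted p under 0.01, alisertib had 440 genes in place of 794 and the difference 19; at 0.1 the difference had 64. A fold of 1.5 in addition left 212 genes with alisertib and 25 in the difference. These stricter and looser thresholds give such changes by construction. With the shared DMSO libraries taken off, the smaller error gave 367 genes in the difference, the main 38 among them, and AURKA passed at the same difference of 0.45. Counts for JB170 stayed at 3 or 4 in the other settings.

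Of the list results, 253 kept their side of the threshold, 21 lost their call and 2 gained one. Direction was compared only where the main or the other setting passed, and it did not turn there. The causes were not tested. With a preset correlation of 0.05, lists past the threshold with alisertib fell to 5 of 9, and adjusted p was 0.208 for heat shock with JB170, and with alisertib 0.0924 for targets and partners, 0.262 for immediate early genes, 0.0561 for myeloid maturation and 0.0515 for heat shock. In the difference it was 0.128 for targets and partners and 0.293 for myeloid maturation. With ranks, it was 0.115 for heat shock with JB170, 0.203 for targets and partners and 0.0785 for immediate early genes with alisertib, and 0.134 for targets and partners in the difference, while ribosomal proteins with alisertib passed at 0.00615. With the log2 fold change as the statistic and a mean log2 CPM of 3 or more, changed together, 1 of 3 lists passed with JB170 and 5 of 9 with alisertib. Adjusted p was then 0.121 for heat shock and 0.0636 for ribosomal proteins with JB170; with alisertib 0.0961 for targets and partners, 0.152 for immediate early genes and 0.110 for both myeloid maturation and heat shock; and in the difference 0.162 for targets and partners and 0.610 for myeloid maturation. Over genes with a mean log2 CPM of 3 or more, immediate early genes with alisertib were at 0.164, myeloid maturation in the difference at 0.0813, and tetraploidy and YAP targets passed with JB170 at 0.0337.

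Among named genes, adjustment over the table left 158 results on their side of the threshold, the minimum mean log2 CPM left 220 and let 5 more pass, and the shared DMSO libraries taken off left 52 and let 27 more pass. What the depth limits is unknown.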

Other observations

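The values below belong to no comparison of the report and were all chosen after the values were seen. In the column headed MK of the authors' deposited table, cytosolic ribosomal protein genes, which encode the parts of the ribosome, were higher as a list (median 0.19, adjusted p = 4.44e-16), as were replication-dependent histones (median 0.58, adjusted p = 1.25e-08) and NF-kB and inflammatory mediators (median 0.18, adjusted p = 4.10e-05). In the same column of the authors' deposited table RN28S1 (1.25, adjusted p = 0.00122), RN7SK (1.14, adjusted p = 5.23e-05) and RMRP (1.04, adjusted p = 0.0268), which like most histone transcripts lack a poly(A) tail, were higher too. The leukaemic HOXA and MEIS1 programme, which keeps such cells immature, was lower in that column (median -0.18, adjusted p = 5.64e-05). The ATF4 and unfolded protein response list was lower in the columns headed MK (median -0.11, adjusted p = 3.64e-06) and A100 (median -0.12, adjusted p = 9.12e-08), and the G2/M and mitosis list was higher in both (0.08, adjusted p = 0.00175, and 0.12, adjusted p = 2.11e-05). With a preset correlation of 0.05 the G2/M and mitosis list lost its call in the column headed MK (adjusted p = 0.107), and the other list results given above for these columns kept theirs. In the column headed A100 the ribosomal protein list was lower (median -0.05, cameraPR adjusted p = 0.0187) and histones were higher (median 0.45, adjusted p = 0.00318). Whether these 2 results hold with a preset correlation of 0.05 is not given here. RN28S1 (1.93, adjusted p = 1.42e-16), RN7SK (1.84, adjusted p = 1.01e-25) and RMRP (2.08, adjusted p = 3.45e-21) were also higher in the column headed A100 of the authors' deposited table. The differences between these columns were not tested.

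FGR, MYBPH, SLC2A5 and CHI3L1, which fell with alisertib, were not called in either of these columns. In the authors' deposited table the log2 changes in the columns headed A100 and MK were -0.21 and 0.09 for FGR, -0.13 and 0.08 for MYBPH, -0.29 and -0.01 for SLC2A5, and 0.02 and -0.07 for CHI3L1. CCNA1, which rose with alisertib, was higher in both columns of the authors' deposited table (0.74, adjusted p = 1.5e-09, and 0.88, adjusted p = 1.33e-06).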
